A study of Mus musculus with 4 samples.

How the data were processed

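RNA of 4 mouse cell populations (MEF, ESC and the lines iPS-OSH and iPS-J) was labelled with Cy3 by a low input amplification kit and hybridized to 1-colour Agilent whole genome arrays, per the labels. Each group held 1 array, all 4 arrays lay on 1 slide, and the scans were made in 3 sessions. The deposited scanner output holds the intensity of each of 62976 spots, which Agilent Feature Extraction 10.5.1.1 background-subtracted and detrended within each array with no normalization between arrays, per the file headers. The deposited value tables hold the same processed intensity on a linear scale, rounded to whole numbers. This was checked on the files, where the rounded values deviated by at most 0.497% from the scanner output. The scanner output of all 4 arrays was used, with its processed signal, mean and background signals, and its calls of spots well above background, saturated or uneven.

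Of 62976 spots, 59305 were not controls, and they held 55681 probes, of which 399 were printed 10 times. Spots called uneven or outlying by the software (203 on the iPS-OSH array, 531 on iPS-J, 390 on ESC and 302 on MEF) were left out, which left 54963 probes with a value on all 4 arrays, and 1 spot was saturated, on the ESC array. Probe coordinates in the files refer to the mm9 assembly and are given as they stand, without exon or UTR, since no annotation of that assembly was used here. Gene names were taken from a reference table by accession for 26419 probes, by symbol for 3993 and by synonym for 826, and 24443 probes kept the name in the file. This gave 35157 genes with a value, of which 31861 were well above background on at least 1 array.

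The log2 processed signal of each array was scaled by subtracting its 75th percentile. Each gene was represented by its brightest probe, the probe with the highest mean over the 4 arrays. A gene entered a comparison if its probe was well above background on at least 1 of the 2 arrays compared. Where it was so on only 1 of them, the difference was taken as a lower bound, against the lowest signal well above background on the dim array or the dim probe's own signal, whichever was higher, and such bounds are given as "at least". Genes were counted as higher or lower at a 2-fold difference, a rule on size alone, since 1 array per group allows no test. All 6 pairs of arrays were compared, and Pearson's r and Spearman's rho were computed across genes well above background on at least 1 of the 4 arrays. The number of arrays limits the precision, and probes printed 10 times give the spot noise within an array.

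A total of 36 gene lists were fixed from general knowledge. They cover pluripotency factors and markers, primed epiblast, the 2-cell stage, germline, fibroblast matrix, mesenchymal identity, epithelium, primitive endoderm, trophoblast, ectoderm, mesoderm, blood, endothelium and muscle. They also cover Hox and imprinted genes, DNA methylation, Polycomb and histone modifiers, cell cycle, senescence, the Hedgehog, Wnt, LIF and transforming growth factor pathways, interferon, antigen presentation, inflammation, metabolism, sex-linked, strain-variable, housekeeping and reprogramming genes. Of 784 memberships, 778 were on the array. For each list the median difference, with bounds taken at their value, was set against 10000 random lists of the same size matched on brightness in 20 bins, and its percentile among them describes these arrays only. Named genes followed a rule. For each comparison it takes the 6 largest measured differences and the 3 largest bounds in each direction, and up to 4 members of each list with the largest differences. It always takes Pou5f1, Sox2, Nanog, Klf4, Myc, Zfp42, Thy1, Col1a1 and Xist, and over the pluripotent arrays it takes the 5 genes that stood farthest from both others, or from MEF on all arrays, in each direction. Genes without a common symbol were not named, and the rule took 417 genes.

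Of the alternatives tried, 9 were chosen with the rest of the design before the data were examined. They were normexp background correction with an offset of 50 (limma 3.58.1), quantile normalization, the 75th percentile over probes detected on all arrays, scaling on the median of 10 Agilent spike-in probes, detection on both arrays, no filter on dim probes, the median over a gene's probes, the deposited value table in place of the scanner output, and a 4-fold threshold. The remaining alternative was chosen after seeing the data and counts a probe as detected only above the 95th percentile of the ERCC control probes of its array. Other detected probes of the genes counted as different went in the same direction in 74.8% to 81.7% of cases and were also at least 2-fold different in 39.3% to 47.0%. The overlap of differences that share an array was set against 100 simulated sets of arrays without a difference.

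The procedure was tested on simulated data, with differences of 1.5 and 3 log2 units in either direction added to 50 genes each among 35157 in 3 of the comparisons and with the spot noise of the arrays. All 50 genes of each set were recovered, except 49 for the upward difference of 1.5 in ESC minus MEF, and 0 of 34957 unchanged genes were called. The changed genes were drawn from brighter genes well above background, and scaling and the choice of probe were not simulated. With noise this small against the added differences, near full recovery was close to fixed in advance. Dim genes with a difference were not tested. The simulation holds spot noise only and not the spread between cultures. Calculations used R 4.3.3, Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Labels give no meaning for OSH or J and name no feeder layer, and neither was assumed.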

Results

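Gene expression was measured in 4 mouse cell populations on 1-colour Agilent arrays. The populations were iPS-OSH and iPS-J, a pair of induced pluripotent stem (iPS) cell lines, embryonic stem cells (ESC) and mouse embryonic fibroblasts (MEF). iPS cells are somatic cells that have been reprogrammed to a state like that of ESC, and MEF are connective tissue cells of the embryo. Both iPS lines and MEF had the C57BL/6 background and ESC the 129SV background, and the pluripotent lines were grown with the cytokine LIF. Each population was measured on 1 array, so no difference has a replicate check and no p-value is given. Of 59305 non-control spots per array, 78.2% were well above background on the iPS-OSH array, 67.0% on the iPS-J array, 78.4% on the ESC array and 81.7% on the MEF array. The 75th percentile of the processed signal, to which each array was scaled, was 1564, 1241, 1307 and 1765 in the same order. The log2 SD between spots of probes printed 10 times was 0.07, 0.09, 0.15 and 0.11, which gives a difference between arrays a technical SD of 0.12 to 0.19. This SD covers spot noise only and leaves out the spread between cultures. The arrays shared 1 slide, but MEF was scanned in session 1, both iPS lines in session 2 and ESC in session 3. Scan session and group therefore cannot be told apart in any comparison with MEF or ESC, whereas iPS-OSH and iPS-J were compared within 1 session. ESC also differed from the other populations in strain, which cannot be told apart from cell type in any comparison with ESC.

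The series set the profiles of the 4 populations against one another, and across 31861 genes the pluripotent lines were closer to each other than to MEF. Pearson's r of the normalized log2 signal was 0.966 between iPS-OSH and iPS-J (Spearman's rho 0.961), 0.955 between iPS-J and ESC (rho 0.949) and 0.942 between iPS-OSH and ESC (rho 0.936). Against MEF, r was 0.918 for iPS-OSH (rho 0.907), 0.885 for iPS-J (rho 0.870) and 0.868 for ESC (rho 0.856), so iPS-OSH was the pluripotent array closest to MEF and farthest from ESC. These correlations run across genes, which are not independent replicates. Dppa5a, a germ cell and pluripotent cell RNA-binding protein, had a signal of 189895 in iPS-OSH, 239881 in iPS-J and 196685 in ESC against 98.5 in MEF. Pou5f1, the transcription factor also called Oct4 (probe on mm9 chromosome 17, positions 35647280 to 35647340), had signals of 10442, 11868 and 7401 against 83.5. Sox2, its partner factor (chromosome 3, positions 34550773 to 34550832), had signals of 14469, 13955 and 17743 and was not well above background in MEF. The fibrillar collagen gene Col1a1 (chromosome 11, positions 94813115 to 94813174) had signals of 59875 in iPS-OSH and 9644 in ESC against 398046 in MEF.

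**Figure D1:**
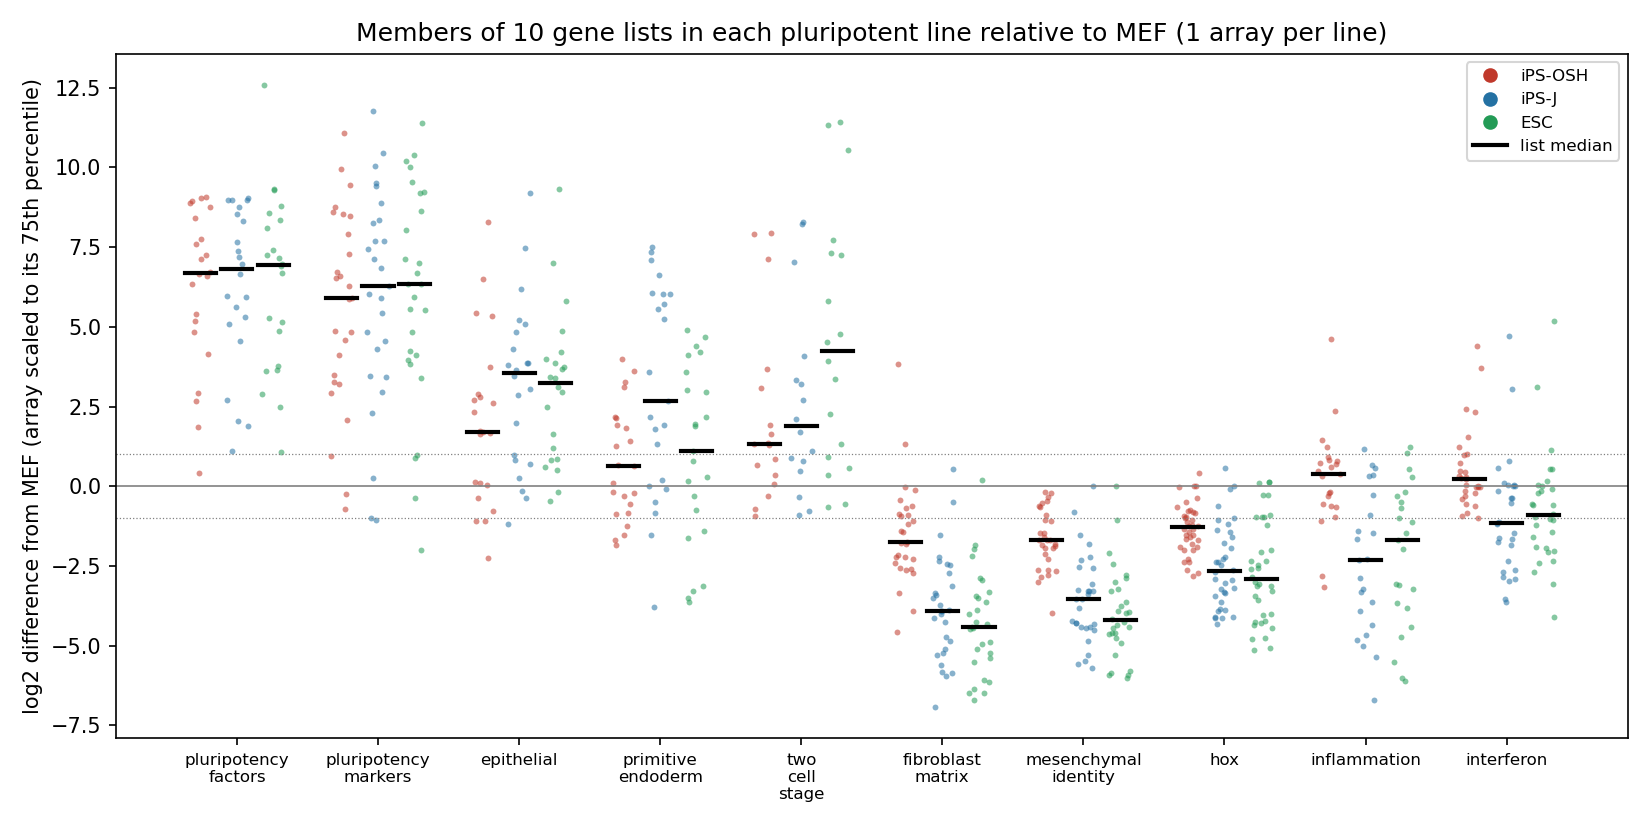
Log2 difference from MEF (vertical axis, each array scaled to its 75th percentile) of the members of 10 gene lists in iPS-OSH, iPS-J and ESC, with 1 point per gene, lower bounds included, a black bar at each list median and dotted lines at 2-fold. Medians of the pluripotency factors were 6.69, 6.82 and 6.93 (6.06, 6.00 and 5.79 with ERCC-based detection), whereas medians of the fibroblast matrix list were -1.74, -3.90 and -4.41.

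The comparison of iPS-OSH with MEF asked which genes set this line apart from fibroblasts. iPS-OSH had far higher signals for the regulators and markers of pluripotent cells and lower signals for most matrix, mesenchymal and Hox genes. Of 22 pluripotency factors, 21 were at least 2-fold higher and 0 lower, with a median log2 difference of 6.69, or 104-fold, at percentile 100 of 10000 random lists matched on brightness. Lower bounds made up 7 of the 22 values, and the median was 6.06 with ERCC-based detection. Of 29 fibroblast matrix genes, 19 were lower and 2 higher (median -1.74, percentile 0), and of 30 mesenchymal genes 22 were lower and 0 higher (median -1.69, percentile 0). Among the pluripotency factors, Nanog was higher by 8.96 and Sall4, a zinc finger factor, by 7.62, while Sox2, Dppa2, Nr0b1 and Tfcp2l1 were higher by at least 8.75, 9.07, 8.88 and 9.06. The other detected probe of Nanog went the opposite way, with a difference of -1.07, and 1 of the 2 other probes of Sall4 did so too, with -0.70. Klf4 and Myc, often used to reprogram cells, lay within 2-fold of MEF, with differences of 0.43 and 0.76. Of 27 further pluripotency markers, 24 were higher (median 5.89), led by Dppa5a at 11.09, the growth factor gene Fgf4 at 9.45, Tex19.1 at 8.76 and Gdf3 at a minimum of 9.95. Outside the lists, Pigp (10.68), Dppa5b (10.68) and L1td1 (8.85) were among the 6 largest measured differences, although the other probe of Pigp lay at -0.98.

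Epithelial genes were also higher in iPS-OSH than in MEF, with 14 of 22 members at least 2-fold higher and 3 lower (median 1.71). The cell adhesion genes Cdh1 and Epcam were higher by at least 8.30 and 6.51, and the epithelial regulator Grhl2 by 5.43. Of 27 detected germline genes, 21 were higher (median 2.69, against 1.33 with ERCC-based detection, which counts only probes above most ERCC control probes), among them the receptor tyrosine kinase gene Kit (5.42) and Mael (4.65), which acts in the piRNA pathway. Of 28 Polycomb, Trithorax and other chromatin regulators, 14 were higher (median 0.98), with Jarid2 at 3.99 and Phc1 at 2.92, and the DNA methylation genes Dnmt3l (6.28), Dnmt3b (5.78) and Tet1 (4.70) were higher too. Tdh, the threonine dehydrogenase of mouse pluripotent cells, was higher by 8.49 and the glucose transporter gene Slc2a3 by 5.88. On the lower side, Col5a2 differed by -4.56, Col3a1 by -3.92 and the matricellular gene Postn by -3.35, while the stromelysin gene Mmp3 was higher by 3.85. Thy1, a fibroblast surface marker, differed by -1.09, Meox2 by -3.96 and Pdgfrb by -2.85. Of 38 detected Hox genes, 25 were lower and 0 higher (median -1.29), including Hoxd10 (-2.82) and Hoxc11 (-2.73). Tnmd, the tenomodulin gene of tendon cells (-6.48), Gjb2 (-6.21), Thbs4 (-6.04) and Lrrc17 (-5.74) had some of the largest measured differences. In all, 3926 of 31161 genes compared were at least 2-fold higher and 7292 lower, so 35.0% of these differences were higher, but at a 4-fold threshold the balance turned, with 1471 higher and 1028 lower. The median over all genes was -0.32, against -0.16 with quantile normalization and -0.49 with spike-in scaling and in the deposited table.

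iPS-J had far higher signals than MEF for pluripotency genes, and its fibroblast genes lay farther below MEF than those of iPS-OSH. All 22 pluripotency factors were at least 2-fold higher (median 6.82, or 113-fold, percentile 100), as were 24 of 27 pluripotency markers (median 6.28). For the factors, 7 of the 22 values were lower bounds, and their median was 6.00 with ERCC-based detection. Of 29 fibroblast matrix genes, 27 were lower and 0 higher (median -3.90, percentile 0), and 28 of 30 mesenchymal genes were lower (median -3.54, percentile 0). Endoderm genes were much higher, with 16 of 23 members of the primitive endoderm list at least 2-fold above MEF and 2 below (median 2.67, percentile 100). Amn and Cubn, which encode the parts of an endocytic receptor of visceral endoderm, were higher by 7.50 and 6.63, the laminin gene Lama1 by 7.34 and the forkhead gene Foxq1 by 7.11. Pou5f1 was higher by 7.66, Nanog by 8.97, and Sox2, Nr0b1 and Dppa4 by at least 9.04, 8.99 and 8.97. For Nanog, the other probe lay at -1.09. Klf4 was 2.14-fold higher, and Myc lay within 2-fold at -0.40. Among markers, Dppa5a was higher by 11.76, Fgf4 by 10.44 and Tdgf1, which encodes a Nodal co-receptor, by 9.52, with Gdf3 at a minimum of 10.04.

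Of 22 epithelial genes, 15 were higher in iPS-J than in MEF and 1 was lower (median 3.56), with the keratin gene Krt8 at 5.23 and Cdh1 at a minimum of 9.19. Cell cycle genes had a median of 1.0 (0.49 in the deposited table), with 15 of 29 higher, among them the spindle checkpoint genes Bub1 (2.22) and Bub1b (2.15), whereas Ccnd2, a D-type cyclin gene, differed by -3.02. Glycolysis genes had a median of 0.79 (0.29 in the deposited table), and Slc2a3 was higher by 7.68 and Pdk1 by 2.59. Matrix genes far below MEF included Postn (-5.96), Col3a1 (-5.86) and Fbln5 (-5.82), and mesenchymal genes included Tbx15 (-5.58), Pdgfrb (-5.48) and Cdh11 (-5.31). Of 23 detected inflammation genes, 16 were lower and 1 higher (median -2.32), with the chemokine genes Cxcl5 at -6.71 and Cxcl12 at -5.37 and the interleukin-33 receptor gene Il1rl1 at -4.82. Of 29 interferon response genes, 16 were lower and 2 higher (median -1.15, against -0.56 with normexp correction), and Ifih1, a sensor of viral RNA, differed by -3.53 while Ifitm1 was higher by 4.72. Hox genes were lower in 31 of 36 cases and higher in 0 (median -2.66), with Hoxa5 at -4.32. In the imprinted Dlk1-Dio3 cluster, 5 of 6 genes were lower (median -1.82), among them Dlk1 (-4.42), Mirg (-2.30) and Meg3 (-1.98). In all, 4907 of 30660 genes were higher and 7241 lower, which made 40.4% of these differences higher (median of all genes -0.19). That share was 29.2% with scaling on the spike-in probes and 19.8% in the deposited value table, where the median of all genes lay at -0.42 and -0.69, but 48.6% with quantile normalization and 51.0% with normexp correction.

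ESC, as the reference pluripotent cells, had high signals for pluripotency genes relative to MEF and the lowest fibroblast matrix median of the 3 pluripotent arrays. All 22 pluripotency factors were at least 2-fold higher (median 6.93, or 122-fold, percentile 100), and 23 of 27 markers were higher (median 6.33). For the factors, 7 of the 22 values were lower bounds, and their median was 5.79 with ERCC-based detection, the lowest of the 3 pluripotent arrays. Of 29 fibroblast matrix genes, 28 were lower (median -4.41, percentile 0), and of 30 mesenchymal genes 29 were lower (median -4.21, percentile 0). Genes of the 2-cell embryo stood out as well, with 13 of 18 detected members higher and 0 lower (median 4.24, percentile 100). As 10 of these 18 values were lower bounds, the median fell to 2.27 with ERCC-based detection and to 1.12 over genes well above background on both arrays. This list is largely made of gene families, such as Zscan4, Tdpoz and Usp17l, whose members are not independent signals. The random lists were not matched on this, here or in the comparisons below. Zscan4e and Zscan4f, zinc finger genes expressed at the 2-cell stage and in a small part of ESC cultures, were higher by at least 11.41 and 11.34. Zfp42, the Rex1 gene used as a marker of undifferentiated ESC, was higher by at least 12.59, Nanog by 9.32 with its other probe at -1.95, and Pou5f1 by 6.90. Fbxo15 was higher by 10.38, Fgf4 by 10.20 and Dppa5a by 11.40. Klf4 was higher by 1.07 and Myc was lower, at -1.98.

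Epithelial genes were higher in ESC than in MEF in 16 of 22 cases and lower in 0 (median 3.25), with Cdh1 at a minimum of 9.33 and the protease inhibitor gene Spint2 at 5.80. Of 29 detected germline genes, 22 were higher (median 3.53), among them Stra8, a gene of meiotic entry, at a minimum of 8.39 and Kit at 7.06. Of 19 trophoblast genes, 13 were higher (median 1.88, against 1.17 with spike-in scaling), including the homeobox gene Rhox9 (7.97) and Tfap2c (7.56). Col5a2 differed by -6.70, the crosslinking enzyme gene Lox by -6.48, Col12a1 by -6.37, and the smooth muscle genes Cnn1, Acta2 and Actg2 by -6.02, -5.91 and -8.06. Transforming growth factor and bone morphogenetic protein genes had a median of -2.35, with 19 of 26 lower, including Tgfb3 (-5.13) and Inhba (-4.99). Of 36 Hox genes, 27 were lower and 0 higher (median -2.92, against -1.71 with ERCC-based detection), with Hoxa11 at -5.15. Inflammation genes were lower in 14 of 23 cases (median -1.69), led by Il1rl1 (-6.11), Cxcl12 (-6.01) and the growth factor gene Csf1 (-4.74). In all, 6843 of 31396 genes were higher and 5172 lower, so 57% of these differences were higher (median of all genes 0.11). That share was 24.8% with spike-in scaling, 35.9% in the deposited table and 67.3% with the percentile taken over probes detected on all arrays, where the median of all genes was -0.56, -0.29 and 0.34.

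The comparisons of the iPS lines with ESC asked how close each came to embryonic stem cells, which also differed from them in strain and scan session. iPS-OSH had most pluripotency factors of ESC at similar signals, but not Zfp42. Its fibroblast, inflammation and interferon response genes stood at higher signals and its 2-cell stage and epithelial genes at lower ones. Of 22 pluripotency factors, 19 lay within 2-fold, 2 were higher and 1 was lower. The lower factor was Zfp42, which stood above both iPS lines in ESC by 4.28 or more. The list median of 0.01 turned sign under quantile normalization and with the percentile taken over probes detected on all arrays. Of 27 further markers, 14 lay within 2-fold, 9 were lower and 4 higher (median -0.31, which turned to 0.22 with spike-in scaling). Among random lists of the same brightness the -0.31 lay at percentile 0.405. Of 29 fibroblast matrix genes, 26 were at least 2-fold higher in iPS-OSH and 0 lower (median 2.89, percentile 100), and of 29 mesenchymal genes 26 were higher and 0 lower (median 2.56, percentile 100). Of 23 inflammation genes, 17 were higher and 0 lower (median 2.69, percentile 100), and of 29 interferon response genes 17 were higher and 0 lower (median 1.21, percentile 100). Of 18 genes of the 2-cell stage, 12 were lower and 0 higher (median -2.97, percentile 0). The small leucine-rich proteoglycan gene Dcn was higher by 4.26, Lox by 4.26, Fbln5 by 4.25 and Col12a1 by 4.21. Among mesenchymal genes, Twist2 was higher by 4.31, Acta2 by 4.09 and the hyaluronan receptor gene Cd44 by 4.07. Thy1 was higher by 2.84 and Col1a1 by 2.38.

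Within the inflammation list, Il1rl1 was higher in iPS-OSH than in ESC by 5.55, Csf1 by 4.57, the prostaglandin synthase gene Ptgs2 by 4.11 and the chemokine gene Ccl2 by 3.87. Ccl11, which encodes the chemokine eotaxin, was higher by at least 5.26. Interferon-induced Ifit3 was higher by 4.38, Ifit1 by 3.31 and Ifi44 by at least 4.31. Of 38 Hox genes, 20 were higher and 2 lower (median 1.24, against 0.75 with normexp correction), with Hoxc9 at 3.45 and Hoxa5 at 3.25. Genes of transforming growth factor and bone morphogenetic protein signalling were higher in 17 of 26 cases (median 1.60), among them the antagonist gene Grem1 (4.13) and Inhba (4.12), and Myc was higher by 2.75. Zfp42 differed by -4.83, the 2-cell stage genes Tcstv3 and Tmem92 by -7.25 and -4.64, and Stra8 by -4.97. Epithelial genes were lower in 11 of 22 cases and higher in 0 (median -1.01, against -0.47 with spike-in scaling), including Tjp3 (-2.35) and Ocln (-2.02), both of tight junctions. The galectin gene Lgals6 (-7.33) and Ppp1r14d, a phosphatase inhibitor gene (-7.56), had the largest measured differences on the lower side. Gc, the vitamin D binding protein gene, was higher by 5.74, but its other detected probe lay at -0.64. Of 30567 genes, 2669 were higher and 8112 lower (24.8% higher, median of all genes -0.28). That share was 47.2% with quantile normalization, 61.9% with spike-in scaling, 40.6% in the deposited table and 17.4% with the percentile over probes detected on all arrays, where the median of all genes was -0.09, 0.24, -0.02 and -0.46, so the balance of higher and lower genes depended on the scaling.

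iPS-J was closer to ESC than iPS-OSH was in its fibroblast, inflammation and interferon genes, and its endoderm genes were higher. Of 22 pluripotency factors, 19 lay within 2-fold of ESC, 1 was higher and 2 were lower, among them Zfp42. The list median of 0.02 turned negative with quantile normalization, in the deposited table and with the percentile over probes detected on all arrays. Among random lists of the same brightness this median was low, at percentile 1.17, with a central range from 0.05 to 0.48. Of 22 primitive endoderm genes, 18 were at least 2-fold higher in iPS-J and 0 lower (median 2.44, percentile 100). Of 27 further markers, 20 lay within 2-fold, 4 were higher and 3 lower. The fibroblast matrix list had a median of 0.45 (percentile 99.65, and 0.91 with spike-in scaling), with 24 of 29 genes within 2-fold, 5 higher and 0 lower. The mesenchymal list had a median of 0.60 (percentile 100), with 19 of 28 genes within 2-fold, 7 higher and 2 lower. Both lists thus stood above random lists of the same brightness, by less than in iPS-OSH. The inflammation list had a median of -0.56, with 14 of 22 within 2-fold, and this median was 0 with ERCC-based detection. Genes of the 2-cell stage were lower in 12 of 18 cases and higher in 0 (median -2.73, percentile 0). Sox7 and Gata4, transcription factor genes of the primitive endoderm, were higher by 3.85 and 3.83, Gata6 by 3.43 and Cubn by 3.60. Dkk1, which encodes a Wnt antagonist, was higher by 3.15. The ubiquitin ligase gene Peli3 was higher by 6.34, the largest measured difference, followed by Gc at 6.16, whose other probe lay at -0.89.

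Zfp42 was lower in iPS-J than in ESC, at -4.28, as were Zscan4c (-3.93), Zscan4a (-3.52), Tmem92 (-3.63) and Tcstv3 (-5.63) of the 2-cell stage list. Of 28 germline genes, 11 were lower and 0 higher (median -0.78, against -0.31 with spike-in scaling), with Stra8 at -4.55 and Dazl, an RNA-binding germ cell gene, at -1.79. Pramel6, a target of LIF signalling, differed by -4.60. The largest measured differences on the lower side were those of Ppp1r14d (-7.49), Lgals6 (-6.54), the chemokine gene Ccl6 (-6.19) and the muscle gene Myom2 (-5.95). In the Dlk1-Dio3 cluster, Mirg differed by -1.49 and Meg3 by -1.24, while Dlk1 lay at -0.05. Nanog (-0.35), Pou5f1 (0.76), Sox2 (-0.27) and Klf4 (0.03) lay within 2-fold, and Myc was higher by 1.58. The other probe of Nanog lay at 0.86. Col1a1 (0.09) and Thy1 (0.41) lay within 2-fold as well. Of 29583 genes, 1589 were higher and 6799 lower (18.9% higher, median of all genes -0.18). That share was 47.7% with quantile normalization and 59.1% with spike-in scaling, where the median of all genes was 0.00 and 0.25, but 15.5% in the deposited table and 11.1% with the percentile over probes detected on all arrays, where it was -0.25 and -0.37.

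iPS-OSH and iPS-J, the pair scanned in 1 session, had similar signals for the pluripotency factors and differed most in fibroblast, inflammation and endoderm genes. All 22 pluripotency factors lay within 2-fold (median -0.07, negative in all settings but quantile normalization and the deposited table), with Pou5f1 at -0.52, Sox2 at -0.28, Nanog at -0.02, Zfp42 at -0.55 and Klf4 at -0.67. Of 27 further markers, 23 lay within 2-fold, and 4 were lower in iPS-OSH and 0 higher (median -0.23, which turned to 0.11 in the deposited table), with Tdgf1 at -1.62. Of 29 fibroblast matrix genes, 27 were at least 2-fold higher in iPS-OSH and 0 lower (median 2.41, percentile 100), and of 29 mesenchymal genes 26 were higher and 1 lower (median 1.91, percentile 100). Of 23 inflammation genes, 18 were higher and 0 lower (median 3.26, percentile 100), and of 28 interferon response genes 15 were higher and 0 lower (median 1.09, percentile 100). Of 22 primitive endoderm genes, 18 were lower in iPS-OSH and 1 was higher (median -2.77, percentile 0). Among matrix genes, Fbln5 was higher by 3.59, Dcn by 3.56, Lox by 3.41 and the tenascin gene Tnc by 3.35, and among mesenchymal genes Twist2 was higher by 3.77 and Cd44 by 3.28. Il6 was higher by 4.39, Il1rl1 by 4.26, the acute phase gene Saa3 by 4.24, Ccl2 by 4.11 and Ifit3 by 4.16. Ccl11 and Ifi44 were higher by at least 5.04 and 4.07. Genes of antigen presentation had a median of 1.0, with 7 of 14 higher, among them B2m, the light chain of class I molecules (3.10), and H2-D1 (2.51).

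Of 19 haematopoietic genes, 8 were at least 2-fold higher in iPS-OSH than in iPS-J and 0 lower (median 0.49, against 0.93 with ERCC-based detection and 0.28 with the median over a gene's probes), with the lysozyme genes Lyz2 at 3.10 and Lyz1 at 2.51 and the adaptor gene Tyrobp at 2.73. The macrophage genes Csf1r and Cd68 lay within 2-fold, at -0.53 and -0.15, but their other probes went the opposite way, at 1.05 and 0.38. Hox genes were higher in 20 of 37 cases and lower in 2 (median 1.20, against 0.47 with normexp correction), led by Hoxc10 (2.89), Hoxc9 (2.78) and Hoxb3 (2.62). Of 6 genes of the Dlk1-Dio3 cluster, 3 were higher (median 1.04, against 1.60 with ERCC-based detection), including the noncoding RNA genes Mirg (2.00) and Meg3 (1.83). Of 27 Wnt pathway genes, 10 were higher and 2 lower (median 0.57, against 0.90 in the deposited table), with Dkk2 higher by 3.27 and Wnt5a by 2.96, but Dkk1 lower at -3.82. Among endoderm genes, Cubn differed by -5.35, Amn by -4.38, Gata4 by -4.29 and Sox7 by -4.21, and outside the list Peli3 by -6.54, the water channel gene Aqp8 by -5.52, Plek2 by -5.37, the proteoglycan gene Srgn by -5.34 and the hexokinase-like gene Hkdc1 by -5.11. Of 22 epithelial genes, 11 were lower and 0 higher (median -1.08), with the keratin gene Krt19 at -2.51 and Cldn3 at -2.15. Glycolysis genes had a median of -0.82 (-0.49 in the deposited table), with 10 of 22 lower and 0 higher, among them Aldoc (-3.07), Slc2a3 (-1.80) and Eno2 (-1.61). The X-inactivation transcript Xist was higher in iPS-OSH than in iPS-J by 2.54, and its signals were 357 in iPS-OSH, 48.8 in iPS-J and 476 in MEF, while it was not well above background in ESC. Of 29242 genes, 2298 were higher and 2129 lower (51.9% higher). That share was 77.5% in the deposited table, whose values are unscaled and where the median of all genes was 0.27.

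**Figure D2:**
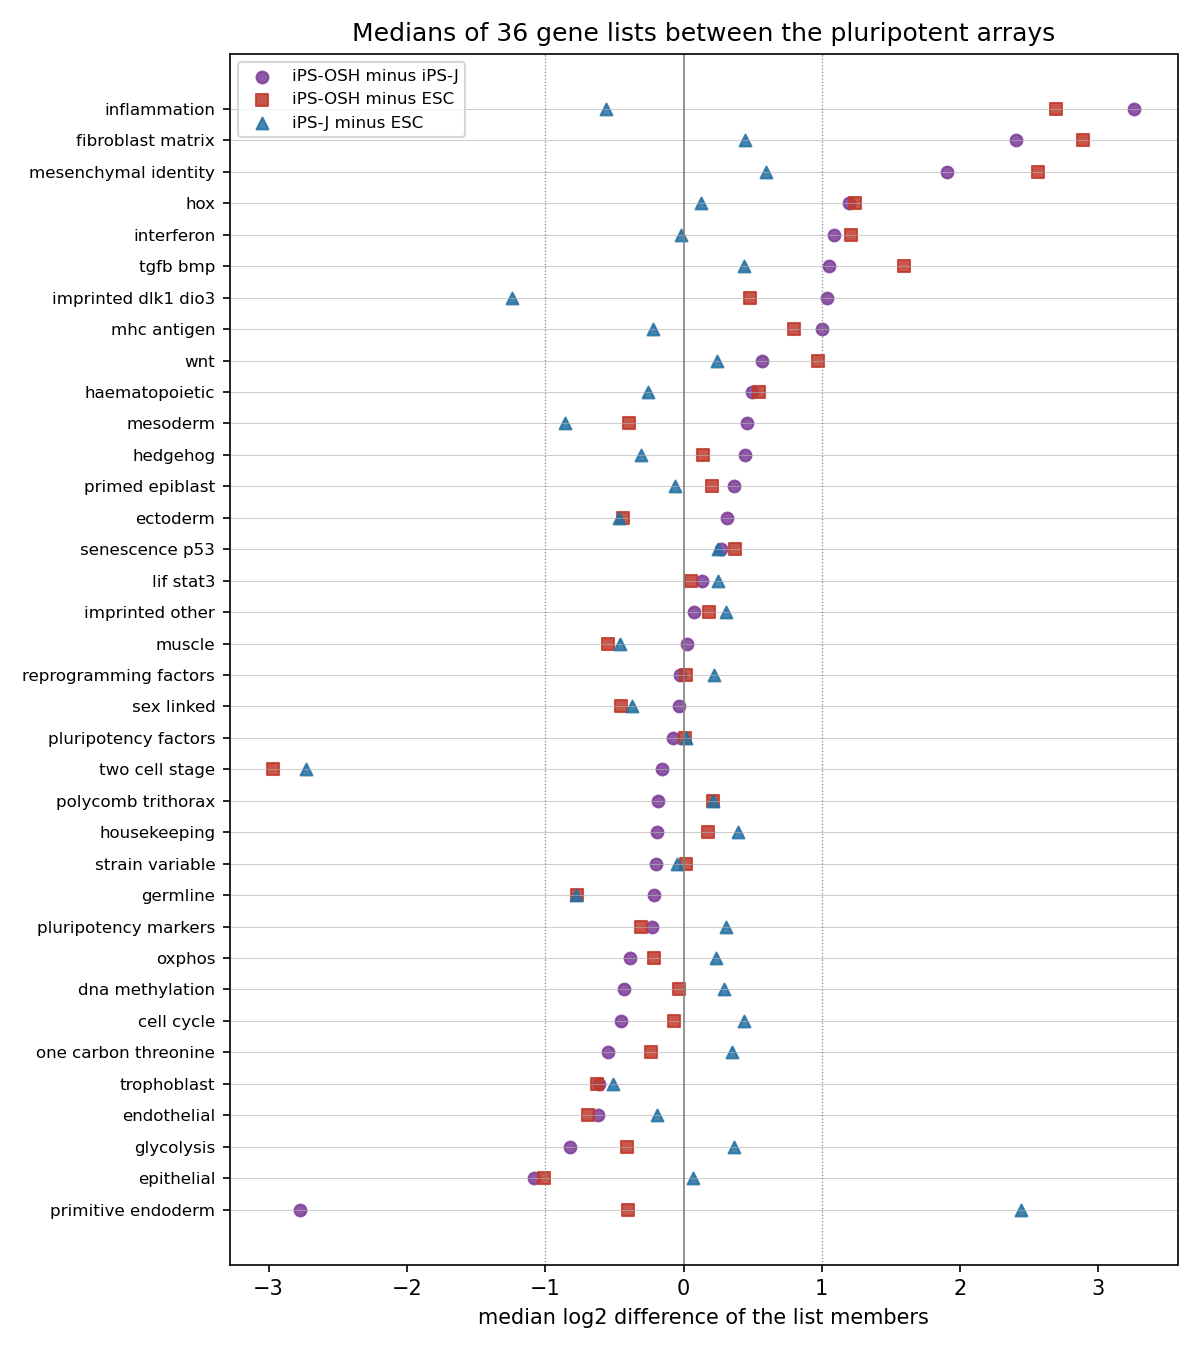
Median log2 difference (horizontal axis) of 36 gene lists between iPS-OSH and iPS-J (circles), iPS-OSH and ESC (squares) and iPS-J and ESC (triangles), with dotted lines at 2-fold and lists ordered by the first of these. The inflammation list lies at 3.26, 2.69 and -0.56 and the primitive endoderm list at -2.77, -0.40 and 2.44, the -0.40 turning positive with spike-in scaling and the -0.56 becoming 0 with ERCC-based detection.

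Set against both other pluripotent arrays, 1365 genes were at least 2-fold higher and 1103 at least 2-fold lower in iPS-OSH, 582 higher and 642 lower in iPS-J, and 5141 higher and 630 lower in ESC. With ERCC-based detection these counts were 998 and 702, 326 and 275, and 3245 and 460 in the same order. The excess of higher genes in ESC depended on the scaling, since spike-in scaling gave 1986 higher and 2697 lower and quantile normalization 2036 and 1406. In iPS-OSH the largest such gaps on the higher side were those of Ccl11, Il1rl1, Ifit3, the protocadherin gene Pcdh7 and Ifi44, with smaller gaps of 5.04, 4.26, 4.16, 4.08 and 4.07, Ccl11 and Ifi44 being lower bounds. On the lower side they were those of Ndufa4l2 (-3.90), the glycogen regulator gene Ppp1r3g (a bound of -3.40), the class II gene H2-Ab1 (-3.32), the histamine synthesis gene Hdc (-3.21) and Aldoc (-3.07). In iPS-J, Peli3 (6.34), the vomeronasal receptor gene Vmn1r205 (a bound of 4.44), Plek2 (4.39), Sox7 (3.85) and Gata4 (3.83) led the higher side, and Ccl6 (-3.78), Tmem132e (a bound of -2.997), the serotonin receptor gene Htr2a (-2.75), Dynap (a bound of -2.69) and Cntfr (a bound of -2.63) the lower side. The other probe of Cntfr went the opposite way, with iPS-J above ESC by 0.50. In ESC, Ppp1r14d (7.49), Lgals6 (6.54), Tcstv3 (5.63), Stra8 (4.55) and Zfp42 (4.28) led the higher side, and Gc (-5.74), Bmper (-3.44), the kinesin gene Kif5b (-3.41), Cst13 (-3.31) and Reg2 (-3.24) the lower side. Against MEF, 2635 of 30439 genes were at least 2-fold higher and 2643 at least 2-fold lower on all 3 pluripotent arrays.

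The differences of the pluripotent lines from MEF ran in parallel, but they share the MEF array and hence its chance values. Across 24562 genes measured on the 3 arrays, the differences of iPS-OSH and iPS-J from MEF correlated at r of 0.856, where arrays without a difference gave 0.50 in simulation, and their covariance was 1.57 against a simulated 0.31. Both lines had 2627 genes higher than MEF in common, where independent lists would share 550 and simulated unchanged arrays 653, and 3773 lower genes in common, against 1214 and 857. For iPS-OSH and ESC r was 0.733 (simulated 0.501) with a covariance of 1.36 against 0.31, and for iPS-J and ESC r was 0.827 (simulated 0.499) with a covariance of 1.93 against 0.31. With ESC as the shared array, the differences of iPS-OSH and iPS-J correlated at r of 0.686 (simulated 0.502, covariance 0.66 against 0.33). They shared 564 higher genes, against 122 for independent lists and 704 in simulation, and 3648 lower genes, against 1103 and 944. Part of each excess may come from the shared array, since 1 array cannot be split, and the simulated spread was taken from iPS-OSH minus iPS-J, which also holds real differences.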

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

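All tests of this part were chosen after the results were seen, except the comparison of counts of ESC-low genes with those of the iPS arrays, whose bound was written before.

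Genes of fibroblasts, inflammation and the interferon response were higher in iPS-OSH than in iPS-J and ESC. As a hypothesis, RNA from fibroblasts like those on the MEF array could be the source of the fibroblast genes, and then they would all stand at the same share of the MEF signal. The share of 513 genes at least 8-fold above iPS-J and ESC in MEF had a median of 21.1% with quartiles of 12.0% and 34.4%, and 62.8% of the genes lay within 2-fold of it, against 90.3% in a simulation with the spread of iPS-J minus ESC. List medians of the share were 20.3% for fibroblast matrix, 24.8% for mesenchymal, 27.5% for Hox and 23.6% for transforming growth factor and bone morphogenetic protein genes, but 67.0% for 9 inflammation genes, and single matrix genes ranged from 3.51% to 99.4%. As a simulated spread cannot stand in for replicate cultures, this source stays open for the fibroblast genes. For inflammation and interferon genes, 29 of 55 members were at least 2-fold above iPS-J and ESC, and 8 of these were also at least 2-fold above MEF (Saa3 by 4.61, Oas1a by 2.43, Mmp13 by 2.37, Ifit3 by 2.32, Irf7 by 1.55, Ccl8 by 1.44, Ccl5 and Ifi44 by 1.23). For these 8 genes this argues against RNA like that of the MEF array as the only source, although MEF was scanned in another session. The rest of the 29 were not 2-fold above MEF, and for them this source stays open. Fibroblasts in another state and expression by the iPS-OSH cells themselves cannot be told apart, since the ratio of 16.5 between the 95th and 5th percentiles of the shares fits either and no other fibroblast culture was measured.

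Genes of the primitive endoderm were higher in iPS-J than in iPS-OSH and ESC. A scan or signal trend of the iPS-J array could raise a list of this brightness, but the median of iPS-OSH minus iPS-J was -2.77 against a central range of random lists from -0.34 to 0.15, within 1 scan session. This argues against a trend with brightness and leaves other effects of the iPS-J array untested. The median had been seen before the test was chosen. Cells with an extraembryonic endoderm programme in the culture may be the source, and of 26 parietal and visceral endoderm genes, listed later, 14 were at least 2-fold above both other arrays. As 13 of these 26 genes are also in the primitive endoderm list, the test was narrowed, after that result, to the remaining 13, of which 6 passed. Srgn, among these 6, is named above for its large difference between the iPS lines, so that part of its result was already seen. The count of 6 lies between the bounds set and leaves the question open. Among those that did not pass, Rbp4 and Apob were lower than in ESC, at -1.33 and -1.06. Apoa2, Apom, Fst and Plat lay within 2-fold of ESC at -0.13, 0.04, 0.30 and 0.49, and Sparc was above iPS-OSH by only 0.35. Of the genes shared with the primitive endoderm list, Thbd (-0.26) and Ttr (0.22) also lay within 2-fold of ESC, and Afp and Apoa1 were near background. Thbd, Fst and Plat are also high in MEF and iPS-OSH.

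Single genes were counted as at least 4-fold lower on the ESC array than on all others, 16 in number, against 3 on the iPS-OSH array and 4 on the iPS-J array. MEF had 525. Genes counted as at least 4-fold higher on 1 array than on all others, without the ERCC-based level, numbered 71 on ESC, 3 on iPS-OSH, 13 on iPS-J and 113 on MEF, and they were not tested. These counts leave out some genes that meet the size rule, since Zfp42 and Stra8 are not among the 71 on ESC. Size was therefore not the only condition for a gene to be counted. The counts of lower genes may be incomplete in the same way, and comparing them between arrays covers only the genes counted. A mismatch of single probes with the 129SV transcript could give this, but all 5 other detected probes (100%) were lower too, and since they belong to only 2 of the 16 genes the mismatch stays open, the need for more genes having been added after that result. A scan or array effect of the ESC array stays open as well, although the ratio of 4 to the larger iPS count met the bound that was to exclude it. That bound was wrong, because the ESC session holds no other array and an array effect would itself raise this count. Strain, scan session and cell type differ together for ESC and cannot be told apart.

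Several lists had medians of opposite sign in the pluripotent lines under the same contrast. These differences were not tested, since each group holds 1 array. Relative to ESC, iPS-OSH and iPS-J stood at -1.01 and 0.070 for epithelial genes, where the 0.070 turned negative with the percentile over probes detected on all arrays. For primitive endoderm genes they stood at -0.40 and 2.44, where the -0.40 turned to 0.13 with spike-in scaling. The Dlk1-Dio3 cluster stood at 0.48 and -1.24, the latter at -0.72 with ERCC-based detection, and inflammation genes at 2.69 and -0.56, the latter at 0 with ERCC-based detection. Interferon response genes stood at 1.21 and -0.020 and antigen presentation genes at 0.80 and -0.22. The iPS-J values of both turned to 0.21 and 0.24 with spike-in scaling. Among brightness-matched random lists, iPS-J lay at percentile 61.95 for epithelial, 82.65 for interferon, 14.92 for antigen presentation and 12.9 for inflammation genes. For primitive endoderm genes, iPS-OSH lay at percentile 12.15. These medians lay within the central range of the random lists. The other medians relative to ESC, except the 0.48 of the Dlk1-Dio3 cluster, lay outside it. Relative to MEF, iPS-OSH, iPS-J and ESC stood at -0.57, -0.42 and 0.62 for ectoderm genes and at -0.61, -0.83 and 0.41 for mesoderm genes. Both ESC values turned negative with spike-in scaling (-0.08 and -0.29), the mesoderm value also with ERCC-based detection (-0.10). Among brightness-matched random lists, the ectoderm medians lay at percentiles 22.66, 29.475 and 91.215. The mesoderm medians lay at percentiles 25.05, 6.22 and 70.12. All lay within the central range, so these sign changes do not set either list apart from random lists. Interferon response genes stood at 0.21 (0.05 with spike-in scaling), -1.15 (-0.56 with normexp correction) and -0.91 (-1.62 with spike-in scaling) and inflammation genes at 0.38 (0.21 with spike-in scaling), -2.32 and -1.69. Antigen presentation genes stood at 0.23 (0.06 with spike-in scaling) in iPS-OSH and -0.85 in iPS-J.

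The arrays also carry 96 ERCC control probes, which the comparisons use only in the ERCC-based detection. Of these, 35 were well above background on the iPS-OSH array, 17 on iPS-J, 49 on ESC and 59 on MEF, with median signals of 20.5, 15.0, 36.9 and 44.8 against 6.37, 8.63, 8.27 and 7.54 for negative control spots. Whether an ERCC mix was added is not given in the sources used here.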

How the results depend on the processing

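The ERCC-based detection was chosen after the results were seen, and the other alternatives before. Of 69 list medians of at least 1 in size, each recomputed under 9 alternatives, 574 of 621 values stayed at least 1 in the same direction, 47 had the same direction but were under 1, and 0 reversed. Over all lists, 1097 of 1944 medians stayed within the technical SD and 847 did not, and the signs that turned belonged to medians under 1 in size. Of 8320 values of named genes 4612 stayed within that SD, 3702 did not, and 6 that had been at least 2-fold different reversed. Of 120 counts 82 stayed within 1.5 times the original, and of 54 correlations 48 stayed within 0.02. No paired analysis was possible because each group holds 1 array. For the values below the cause was not tested, except that a stricter threshold must lower a count. Signal near background limits dim genes, which have lower bounds.

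With a 4-fold threshold, higher and lower counts were 1471 and 1028 in iPS-OSH minus MEF, 2036 and 2110 in iPS-J minus MEF, 2628 and 2072 in ESC minus MEF, 771 and 1470 in iPS-OSH minus ESC, 265 and 1170 in iPS-J minus ESC, and 606 and 425 in iPS-OSH minus iPS-J. With spike-in scaling they were 3458 and 10504 in ESC minus MEF, 6073 and 3740 in iPS-OSH minus ESC, and 4927 and 3406 in iPS-J minus ESC. In the deposited table they were 3007 and 12207 in iPS-J minus MEF, 4476 and 7995 in ESC minus MEF, and 4099 and 1192 in iPS-OSH minus iPS-J. Quantile normalization gave 4057 and 4543 in iPS-OSH minus ESC and 2766 and 3033 in iPS-J minus ESC. With the percentile over probes detected on all arrays, 1054 genes were higher in iPS-J minus ESC. Normexp correction gave 4158 lower genes in iPS-OSH minus MEF, 4160 in iPS-J minus MEF and 3224 in iPS-J minus ESC, and 1434 higher genes in iPS-OSH minus iPS-J, where no filter on dim probes gave 4250. With ERCC-based detection, lower counts were 4771 in iPS-OSH minus MEF, 4704 in iPS-OSH minus ESC and 4153 in iPS-J minus ESC, and 4550 genes were higher in ESC minus MEF.

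Counts against both other pluripotent arrays are not among the 120. In iPS-OSH, 2168 genes were higher and 563 lower in the deposited table, and lower counts were 666 with normexp correction, 607 with spike-in scaling and 702 with ERCC-based detection. In iPS-J, 939 were higher with spike-in scaling, 326 were higher and 275 lower with ERCC-based detection, and lower counts were 126 with normexp correction, 264 with quantile normalization, 2142 with no filter on dim probes and 1370 in the deposited table. In ESC, 2542 were higher with normexp correction and 3245 with ERCC-based detection, higher and lower counts were 2036 and 1406 with quantile normalization and 1986 and 2697 with spike-in scaling, and 369 were lower with the percentile over probes detected on all arrays.

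The correlation with MEF across genes was 0.895 for iPS-OSH, 0.843 for iPS-J and 0.826 for ESC with ERCC-based detection, 0.908 for iPS-J and 0.892 for ESC with normexp correction, and 0.894 for ESC with no filter on dim probes. The median over a gene's probes reversed Ahcy in iPS-J minus ESC (-0.045) and iPS-OSH minus ESC (-0.17), Ftx in ESC minus MEF (-0.25), Gas1 in iPS-OSH minus MEF (0.23), Hhat in iPS-OSH minus ESC (0.025) and Il1rl1 in iPS-J minus ESC (-0.71).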

Other observations

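No test was run for the values of this part, which were described after the results were seen. All pluripotent arrays had high signals for most genes of the primed epiblast list relative to MEF. At least 2-fold higher were 9 of 12 detected genes in each iPS line and 10 of 13 in ESC, with 2 lower on each array. List medians were 3.90 in iPS-OSH, 3.79 in iPS-J and 3.17 in ESC, or 2.69, 2.47 and 2.62 with ERCC-based detection. The transcription factor gene Tcf15 was higher by 8.33, 9.38 and 8.72 and Otx2 by 4.66, 5.08 and 5.49 in the same order. Genes whose products are used to reprogram cells had medians of 2.29, 2.29 and 2.40, with Mycn higher by 6.66, 7.40 and 7.40 and the nuclear receptor gene Nr5a2 by 7.25, 6.65 and 7.27, while the chromatin protein gene Hmga2 differed by -1.47, -3.52 and -3.78. In the LIF and STAT3 pathway, the homeobox gene Gbx2 was higher by 6.57, 6.87 and 5.38. In the Wnt pathway, Tcf7 was higher by 5.28, 5.67 and 6.04 and Lgr5, a stem cell receptor gene, lower with -4.81, a bound of -6.10, and -5.78. Among genes of one-carbon and threonine metabolism, the glycine cleavage gene Gldc was higher by 3.50, 5.43 and 5.92.

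Imprinted genes outside the Dlk1-Dio3 cluster went both ways relative to MEF. Phlda2 was higher by at least 5.66, 7.44 and 6.16 in iPS-OSH, iPS-J and ESC, whereas the growth factor gene Igf2 differed by -2.81, -3.57 and -4.21. Peg3, a paternally expressed zinc finger gene, was higher than in ESC by 2.41 in iPS-J and differed from MEF by 1.96, 1.37 and -1.04. The endothelial gene Robo4 was higher by 5.08, 5.30 and 6.23. Among muscle genes, the embryonic myosin gene Myh3 was higher by 2.48, 4.28 and 6.55 and the actin gene Acta1 lower with -3.04, -5.03 and -6.48. Cdkn2b, which encodes an inhibitor of cyclin-dependent kinases, was lower with -1.56, -3.48 and -4.37. Respiratory chain genes had medians of -0.05, 0.33 and 0.19 and widely expressed genes -0.13, 0.15 and 0.07, each of which turned sign with another scaling or, for the 0.33, in the unscaled deposited table.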
